A study of Homo sapiens with 43 samples.

How the data were processed

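The cells were HEL, a human erythroleukemia line, stably transduced with wild-type U2AF1 (WT) or with U2AF1 carrying S34F or Q157R, and the exogenous protein was induced with doxycycline at 1 µg/ml for 48 hours, per the labels. U2AF1 and U2AF2 are the small and large subunits of the factor that recognises the 3' splice site. Of the 43 samples of the series, 34 were analysed: 10 RNA-seq libraries made after rRNA depletion, 7 eCLIP libraries and 17 freCLIP libraries. In eCLIP, RNA crosslinked to a protein by ultraviolet light is sequenced after immunoprecipitation, here with 12 µg of anti-FLAG antibody for U2AF1 or 8 µg of anti-U2AF2 antibody, per the labels' protocols. In freCLIP the membrane was divided into a light fraction of 37 to 65 kD and a heavy fraction of 65 to 110 kD. The 9 TimeLapse-seq samples were not analysed here.

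The deposited values were raw read counts per annotated gene for each library, and the sums of the columns and the integer values showed no normalization. The submitters' processing notes name cutadapt, STAR 2.7.0f and 2.5.3a, HISAT2, HTSeq, SAMtools, edgeR and DESeq2, with genome build GRCh38.p10, without a role for each tool. Neither the annotation release nor the strand setting of the counting was stated. Each table held 58347 annotated gene entries and closing lines for reads that named no gene, which were left out of library sizes and tests. Gene IDs without version were matched to GENCODE release 29 (58084 entries matched), which gave symbols, gene types and coordinates on GRCh38, counted from 1. Counts that named a gene were 43.6% to 56.1% of the reads in the RNA-seq tables, 1.22% to 1.89% in eCLIP and 0.856% to 1.91% in freCLIP. Reads were counted without molecular identifiers in the tables, so counting intervals and floors cover counting error only.

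Differential tests used edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with its minimum count of 10, and the robust quasi-likelihood F test on a model with one mean per group, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All libraries of an assay were fitted together, so that groups with 1 library borrowed the spread of the others. RNA-seq had 6 groups, freCLIP had 6 groups, and the 3 eCLIP libraries named as technical replicates were summed into their biological replicate. The light fraction relative to RNA was tested as the interaction of assay and genotype in a joint fit. The labels call the replicates biological but do not say that they were separate cultures, so the p-values measure a spread between samples that may be technical in part. Levels are counts scaled by library size with TMM (CPM), given as mean ± SD, and log2 fold changes are given with their standard error (SE). Where a CLIP group had no count, a bound was computed from 3 counts over the group's summed libraries. Where it had 1 to 3 counts, the ratio is given with its 95% exact binomial interval. Spearman coefficients between libraries of a group were taken over entries with at least 10 counts in the 2 libraries together.

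Before the data were examined, 26 gene lists and a rule for named genes were fixed. The lists were stress granule proteins, integrated stress response and ATF4 targets, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, cytosolic ribosomal proteins, the U2 snRNP and 3' splice site recognition, SR proteins, hnRNP proteins, nonsense-mediated decay (NMD) factors, NMD-sensitive transcripts, erythroid markers, megakaryocyte and platelet markers, monocyte and granulocyte markers, lymphoid markers, stromal and epithelial markers, p53 targets, proliferation genes, interferon-stimulated genes, heat shock and cytosolic chaperones, the endoplasmic reticulum (ER) unfolded protein response, cholesterol synthesis, inflammatory and NF-kB targets, genes recalled as alternatively spliced in U2AF1-mutant cells, JAK-STAT targets, abundant nuclear small RNAs, and nuclear-retained long noncoding RNAs (lncRNAs). Each list with at least 5 tested members was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The rule named U2AF1 and U2AF2 first. It then took, among called genes with mean log2 CPM of at least 3, a symbol that is not a clone name, no pseudogene and no overlap between the libraries of the groups, the 6 largest rises and the 6 largest falls (4 each in tests of a difference). From each list it took up to 3 called members with the lowest adjusted p, or, with none called, the 2 most abundant members. Genes on the Y chromosome and XIST were left out.

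The alternatives fixed in advance were the replicate number as a block, DESeq2 1.42.0 (Wald test), its size-factor scaling (RLE) within edgeR, no filter on low counts, only the compared groups in the fit, nuclear chromosomes only, only the eCLIP libraries named as biological replicates, voom with a variance per assay, the estimated correlation, and each replicate left out in turn. In RNA-seq, libraries with the same replicate number deviated together from their group means, with correlations of 0.211 to 0.652 in 12 of 12 pairs. In groups of 2 libraries the deviations mirror each other, so each coefficient appears for replicate 1 and again for replicate 2. The numbers thus pair these libraries by the data and not by the labels. Chosen after seeing the data were the replicate block with a correction for GC content and exon length, the same naming rule applied to the fit with the replicate block, CLIP entries under 1 opposite-strand gene only, the technical libraries of U2AF1 replicate 1 in place of its replicate 2, RNA of the opposite-strand gene in the joint fit, and lists assigned by the opposite-strand gene. GC content and exon length came from the transcripts of the annotation (21205 of 21300 genes).

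The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold, drawn from the means and library sizes of each comparison. In the RNA-seq comparison of S34F with WT, over 20947 genes, 5% of the 2-fold and 51% of the 4-fold changes were recovered. Of its 64 calls 8 were false. In the heavy fraction, S34F against WT, 0% and 8% were recovered over 6419 entries, and in light against heavy WT 0% and 3% over 6433 entries. In the light fraction, S34F against WT (6406 entries), in eCLIP (9977 entries) and in the light fraction relative to RNA, S34F against WT (10510 entries), 0% were recovered at either size.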

Results

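HEL erythroleukemia cells that carried WT, S34F or Q157R U2AF1 were profiled by RNA-seq, eCLIP and freCLIP. RNA-seq covered 2 uninduced and 2 induced WT libraries, 1 uninduced and 2 induced S34F libraries, and 1 uninduced and 2 induced Q157R libraries. The uninduced S34F and Q157R groups had no replicates. Gene counts per RNA-seq library were 24866906 and 32127920 in uninduced WT, 40370092 and 27795768 in induced WT, 36871904 in uninduced S34F, 22392303 and 26939189 in induced S34F, 28801851 in uninduced Q157R, and 27127150 and 27581258 in induced Q157R. The eCLIP libraries, all from induced WT cells, held 306711 to 1148212 gene counts, with 3 libraries for U2AF1 (2 biological and 1 technical replicate) and 4 for U2AF2 (2 biological and 2 technical). The freCLIP libraries held 38415 to 730996 gene counts. The light fraction had 3 WT, 3 S34F and 2 Q157R libraries, and the heavy fraction had 4, 3 and 2.

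U2AF1 itself stood at 15.1 ± 6.04 CPM in induced WT cells, 18.4 ± 1.19 CPM in induced S34F cells and 18.3 ± 4.81 CPM in induced Q157R cells (SD, n = 2 each, from all libraries scaled together). Uninduced cells held 12.98 ± 0.502 CPM in the WT line (n = 2), 21.7 CPM in the S34F line and 22.3 CPM in the Q157R line. The difference between S34F and WT was 0.31 ± 0.29 on the log2 scale (edgeR adjusted p = 0.547), between Q157R and WT 0.28 ± 0.29 (edgeR adjusted p = 1), and between induced and uninduced WT cells 0.21 ± 0.29 (edgeR adjusted p = 0.926). The counts of U2AF1 did not show the induced transgene, and U2AF1L5, a near-identical copy in the annotation that can share its reads, held 9 to 38 counts per library. U2AF2 stood at 329 ± 77.5 CPM in WT, 186 ± 37.3 CPM in S34F and 297 ± 73.2 CPM in Q157R induced cells. The S34F level was lower by -0.79 ± 0.24 (edgeR adjusted p = 0.112), and with the replicate number as a block by -0.79 ± 0.13 (edgeR adjusted p = 0.00231, range over the alternatives 0.00231 to 0.394).

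Induced S34F cells were compared with induced WT cells to ask which transcripts the S34F protein moved. TECTA, which encodes alpha-tectorin of the inner ear matrix, rose 12.7-fold, from 2.55 ± 0.736 to 32.4 ± 11.3 CPM (SD, n = 2 each). AVIL, which encodes the actin-binding protein advillin, rose 9.78-fold, from 4.09 ± 0.315 to 40.1 ± 11 CPM. MXD4, a MAX partner that opposes MYC, rose 4.29-fold to 50.1 ± 4.53 CPM. UBASH3B, a phosphatase that dampens receptor tyrosine kinase signalling, fell 4.92-fold, from 455 ± 13.3 to 92.5 ± 25.1 CPM. TIMP3, an inhibitor of matrix metalloproteinases, fell 4.59-fold, from 2177 ± 722 to 474 ± 52.5 CPM.

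In log2 terms the changes were 3.66 ± 0.41 for TECTA (ENSG00000109927.9; GRCh38 chromosome 11, 121101173 to 121191493; edgeR adjusted p = 0.0347) and 3.29 ± 0.32 for AVIL (ENSG00000135407.10; chromosome 12, 57797376 to 57818704; edgeR adjusted p = 0.0342). They were -2.30 ± 0.21 for UBASH3B (ENSG00000154127.9; chromosome 11, 122655675 to 122814473; edgeR adjusted p = 0.0342) and -2.20 ± 0.34 for TIMP3 (ENSG00000100234.11; chromosome 22, 32801701 to 32863043; edgeR adjusted p = 0.0443). NAALAD2, C20orf204 and MSH4, a meiotic recombination gene, also rose, by 4.51-fold, 4.27-fold and 4.12-fold. CCND1 (cyclin D1) fell 3.99-fold, the histone gene H4C9 3.57-fold, MYEOV 3.32-fold and FAH, the last enzyme of tyrosine catabolism, 3.29-fold. AVIL and TIMP3 lie partly across TSFM and SYN3 on the opposite strand, and the strand setting of the counting was not stated.

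Camera sets each list against all other genes tested. In this comparison the 13602 protein-coding genes had a median log2 fold change of -0.16 and 1555 lincRNA entries one of +0.44. Lists of protein-coding genes are thereby favoured to be called lower, and lists of lncRNAs higher. Genes of cell division were lower as a group. Of 40 proliferation genes, 4 fell, 16 when adjusted over the list alone, with a median log2 fold change of -0.57 (camera adjusted p = 7.3e-07, and adjusted p = 0.393 with an estimated correlation). TOP2A fell 2-fold, from 424.5 ± 53.7 to 212 ± 10.3 CPM, MCM2 2.25-fold, MCM6 2.63-fold and TYMS by 1.01 ± 0.15 on the log2 scale. JAK-STAT targets had the lowest median, -1.17, with 14 of 15 members lower, 0 called and 7 adjusted over the list alone (camera adjusted p = 4.99e-06, and adjusted p = 0.476 with an estimated correlation). Among them MYC was at -1.31, PIM2 at -1.48 and PIM1 at -1.59, and 10 members fell with the replicate block. For integrated stress response and ATF4 targets the median was -1.15, with 26 of 27 members lower, 0 called and 0 adjusted over the list alone (camera adjusted p = 2.79e-04, and adjusted p = 0.73 with an estimated correlation). PSAT1, of serine synthesis, and SHMT2, of one-carbon metabolism, were at -1.97 and -1.09, and 15 members fell with the replicate block. Without WT replicate 2 PIM1 was at -0.90 and PSAT1 at -0.54, and without S34F replicate 2 PSAT1 was at -3.47.

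Metabolic and secretory groups were lower too. Cholesterol synthesis genes had a median of -0.80 with 21 of 22 lower, 0 called and 3 adjusted over the list alone (camera adjusted p = 7.89e-06, and adjusted p = 0.651 with an estimated correlation), SQLE being at -1.37 and FDPS at -1.08. The ER unfolded protein response had a median of -0.71 with 19 of 21 lower, 0 called and 5 adjusted over the list alone (camera adjusted p = 9.06e-05, and adjusted p = 0.393 with an estimated correlation). Its chaperone HSPA5 was at -1.02 and EDEM1 at -1.15. Nuclear oxidative phosphorylation genes had a median of -0.44 with 36 of 38 lower, 0 called and 10 adjusted over the list alone (camera adjusted p = 7.3e-07, and adjusted p = 0.476 with an estimated correlation), and CYC1 was at -0.86. Cytosolic ribosomal proteins had a median of -0.25 with 72 of 78 lower, 0 called and 0 adjusted over the list alone (camera adjusted p = 0.00131, and adjusted p = 0.737 with an estimated correlation). That median lay near the -0.16 of all protein-coding genes. Mitochondrially encoded mRNAs, by contrast, had a median of +0.37 with 13 of 13 higher (camera adjusted p = 0.098; with the block camera adjusted p = 0.0461, and adjusted p = 0.729 with an estimated correlation).

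Blood lineage markers moved in part. Megakaryocyte and platelet markers had a median of -0.56 with 21 of 24 lower (camera adjusted p = 4.19e-04, and adjusted p = 0.333 with an estimated correlation). ITGB3, the platelet fibrinogen receptor's beta chain, fell from 249 ± 5.52 to 129 ± 2.86 CPM and was the only member called, with 5 adjusted over the list alone. RAB27B and GP9 were at -1.11 and -0.85. GFI1B, a repressor needed in erythroid and megakaryocytic cells, fell 2.81-fold and was the only erythroid marker called of 31, also adjusted over the list alone (median -0.04, camera adjusted p = 0.426). ITGAM, which encodes the myeloid integrin CD11b, rose 2.82-fold, from 12.5 ± 3.09 to 35.2 ± 7.8 CPM, the only one of 11 monocyte and granulocyte markers called (median -0.36, camera adjusted p = 0.86). KLRD1, a natural killer cell receptor chain, rose 16.8-fold to 9.09 ± 2.92 CPM, the only one of 11 lymphoid markers called (median -0.11, camera adjusted p = 0.128). Of 9 stromal and epithelial markers 0 were called, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.568).

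Among RNA-processing groups, hnRNP proteins had a median of -0.40 with 24 of 27 lower (camera adjusted p = 0.00131, and adjusted p = 0.393 with an estimated correlation). HNRNPAB fell 2.51-fold, the only member called, with 1 higher and 4 lower adjusted over the list alone. The U2 snRNP and 3' splice site list had a median of -0.39 with 22 of 26 lower, 0 called and 0 adjusted over the list alone (camera adjusted p = 0.00668, and adjusted p = 0.73 with an estimated correlation), SF3B6 being at -0.79. Nuclear-retained lncRNAs had a median of +0.39 with 8 of 10 higher, 0 called and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0354, and adjusted p = 0.393 with an estimated correlation). FTX and TUG1 were at +0.89 and +0.53, and OIP5-AS1 at -0.77. The median of this list was no higher than the +0.44 of lincRNA entries in general. Inflammatory and NF-kB targets had a median of -0.48 with 15 of 18 lower, 0 called and 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.73 with an estimated correlation), with IL6 at -1.57 and CXCL2 at -1.04.

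The other lists were not called by camera. Of 23 p53 targets, the death receptor gene FAS rose from 0.118 ± 0.115 to 4.02 ± 0.161 CPM and GADD45A fell 1.91-fold (median -0.37, camera adjusted p = 0.099). The 25 interferon-stimulated genes had a median of -0.04 (camera adjusted p = 0.605). STRAP fell 2.19-fold, from 182.5 ± 10.2 to 83.2 ± 6.16 CPM, among 16 genes recalled as alternatively spliced in U2AF1-mutant cells (median -0.12, camera adjusted p = 0.174). Medians were -0.17 for stress granule proteins (camera adjusted p = 0.0741), -0.30 for heat shock genes (0.22), +0.06 for SR proteins (0.992), -0.15 for NMD factors (0.151), +0.13 for NMD-sensitive transcripts (0.769) and -0.28 for abundant nuclear small RNAs (0.568).

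In all, 356 of 21300 genes were called between S34F and WT, 145 higher and 211 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Each of the 356 differed in the same direction between replicates 1 and between replicates 2, which a call on these same libraries favours. Over all genes the ratios of the 2 pairs correlated at 0.654. The replicate number separated the RNA-seq libraries: residuals of like-numbered libraries correlated across genes at r = 0.211 to 0.652 in 12 of 12 pairs. Each coefficient appears for replicate 1 and again for replicate 2, whose residuals mirror each other. With the replicate number as a block 4779 genes were called, 2036 higher and 2743 lower. DESeq2 called 1567 and no filter on low counts gave 2410, but 0 were called with only the S34F and WT libraries in the fit, or after leaving out S34F replicate 1, S34F replicate 2, WT replicate 1 or WT replicate 2. The share of reads outside annotated features was 33.6 ± 0.14% in induced S34F libraries and 22.7 ± 0.029% in induced WT libraries (SD, n = 2 each), and it moved with all of these gene groups.

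**Figure D1:**
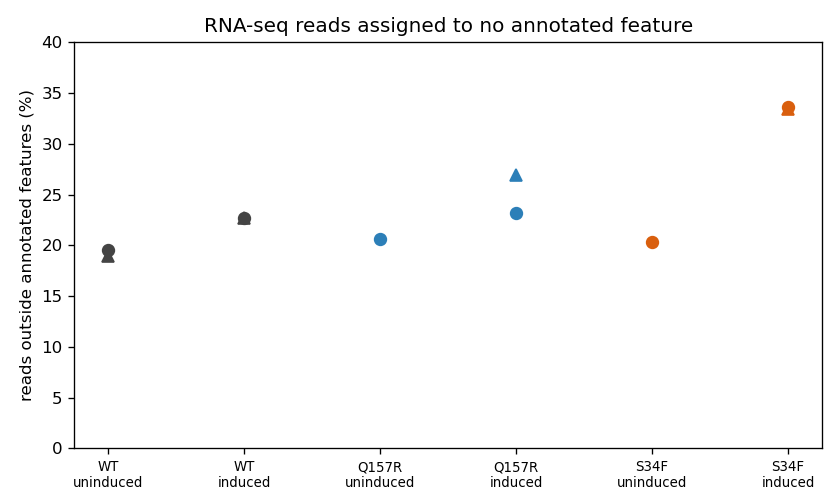
Percent of reads outside annotated features in each RNA-seq library, by group. The induced S34F libraries lie at 33.5% and 33.7%, above all 8 others, the highest of which is Q157R replicate 2 at 27.0%.

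**Figure D2:**
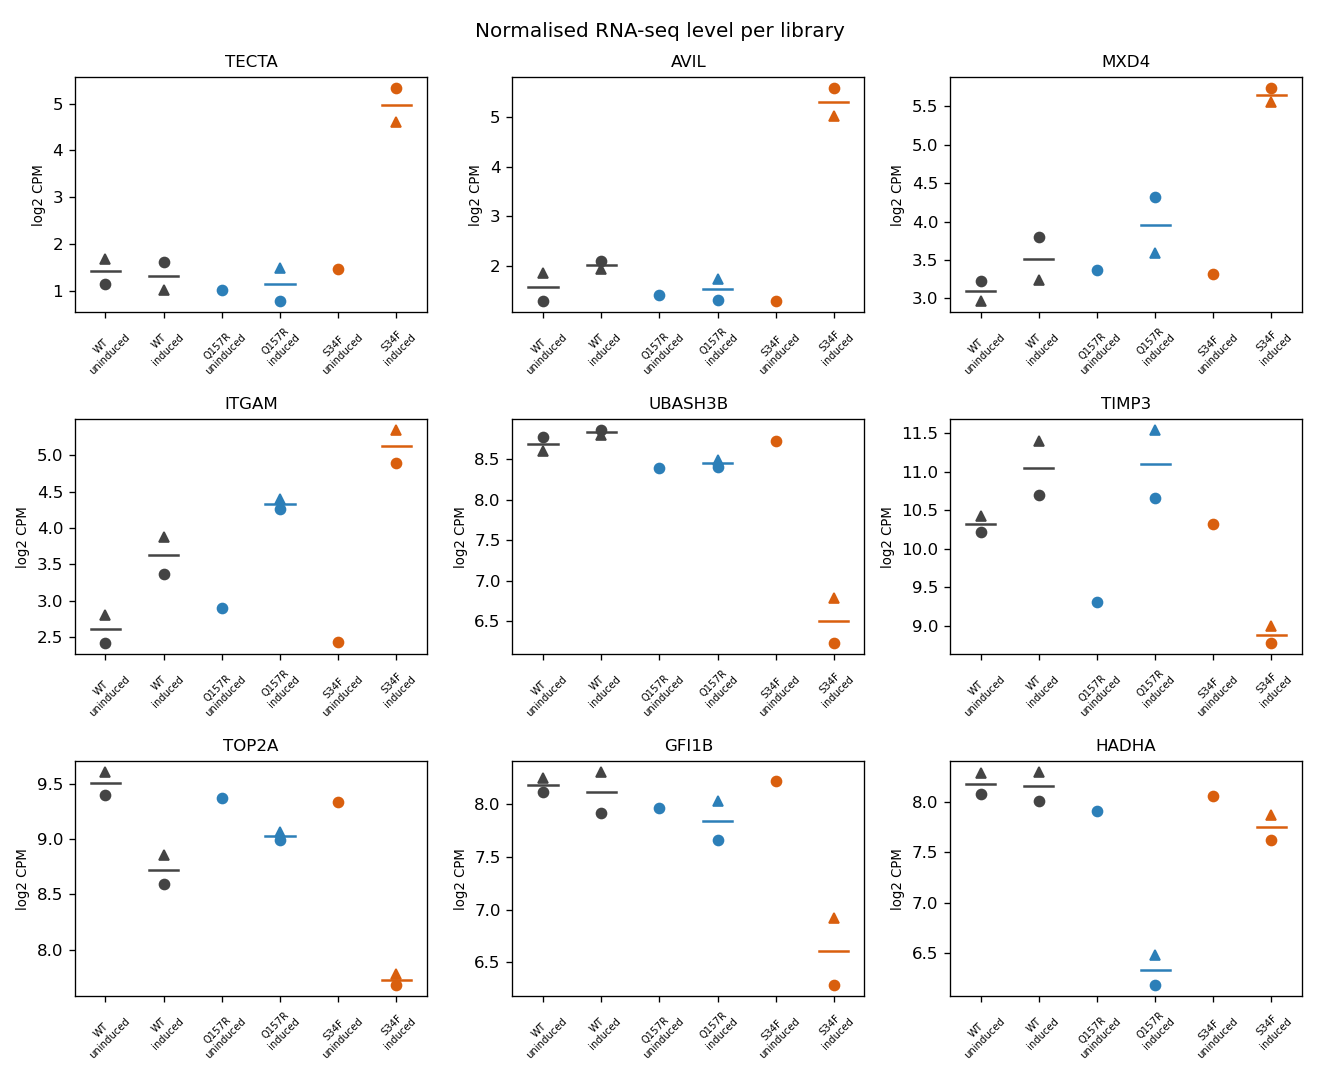
Level of 9 named genes in each RNA-seq library, in log2 CPM, for the 6 groups of genotype and induction. Circles are replicate 1, triangles replicate 2 and lines the mean of a group; TECTA stands at 32.4 CPM on average in induced S34F cells against 2.55 CPM in induced WT cells, and HADHA is lowest in induced Q157R cells.

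Induced Q157R cells differed less from induced WT cells. HADHA, the alpha subunit of the mitochondrial trifunctional protein of fatty acid oxidation, stood at 80.8 ± 11.9 CPM in Q157R and 287 ± 40.6 CPM in WT cells (SD, n = 2 each), 3.55-fold lower. SAMHD1, a dNTP hydrolase that restricts retroviruses, stood at 4.80 ± 1.15 against 19.6 ± 7.76 CPM, and the interferon-induced gene HERC6 at 11.8 ± 2.47 against 29.2 ± 5.2 CPM. STAT2 stood at 74.4 ± 2.87 against 109 ± 3.49 CPM, not called. MALAT1 stood at 4144 ± 336 against 3377 ± 479 CPM, also not called.

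Of 21300 genes, 0 were called between Q157R and WT by edgeR, while 716 had an unadjusted p under 0.05 and DESeq2 called 3. With the replicate number as a block 4 genes fell, among them HADHA (ENSG00000084754.10; chromosome 2, 26190635 to 26244726) at -1.83 ± 0.13 (edgeR adjusted p = 1.7e-04, range over the alternatives 5.48e-11 to 1). SAMHD1 was then at -2.01 ± 0.22 (edgeR adjusted p = 0.011, range 3.29e-06 to 1) and HERC6 at -1.32 ± 0.16 (edgeR adjusted p = 0.0247, range 0.0132 to 1). No filter on low counts gave 15 calls. Cytosolic ribosomal proteins had a median of -0.13 with 69 of 78 lower, 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0192, and adjusted p = 0.949 with an estimated correlation). The other 25 lists were not called, the lowest camera adjusted p being 0.102. With the block mitochondrially encoded mRNAs at +0.27 (camera adjusted p = 0.00361), megakaryocyte markers at -0.18 (0.0462) and the ER unfolded protein response at -0.14 (0.037) were called too, each with adjusted p = 0.874 with an estimated correlation.

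The mutants were also set directly against each other. TECTA was 14.2-fold and AVIL 13.7-fold higher in S34F than in Q157R cells, and ALPK3, a kinase gene of striated muscle, was 6.81-fold higher (49.4 ± 14.8 against 7.25 ± 1.26 CPM, SD, n = 2 each). MSH4, NAALAD2 and NEB (nebulin) were 6.55-fold, 4.71-fold and 4.3-fold higher, and KLRD1 22.7-fold. CCND1 was 5.21-fold lower in S34F, TIMP3 4.84-fold, UBASH3B 3.77-fold and the histone genes H2BC10 and H4C9 3.71-fold and 3.31-fold. AEBP1 was 3.23-fold lower, and TOP2A was lower by -1.30 ± 0.17 on the log2 scale (edgeR adjusted p = 0.0391; 212 ± 10.3 against 521.5 ± 17.5 CPM).

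Proliferation genes had a median of -0.70 with 38 of 40 lower in S34F than in Q157R, 1 called and 16 adjusted over the list alone (camera adjusted p = 1.51e-10, and adjusted p = 0.359 with an estimated correlation). The median was -0.86 for JAK-STAT targets (4 adjusted over the list alone; camera adjusted p = 4.49e-05, and adjusted p = 0.572 with an estimated correlation) and -1.06 for integrated stress response targets (camera adjusted p = 0.00103, and adjusted p = 0.724 with an estimated correlation). It was -0.43 for oxidative phosphorylation (camera adjusted p = 1.64e-06), -0.51 for the ER unfolded protein response (1 adjusted over the list alone; camera adjusted p = 0.00241), and each had adjusted p = 0.572 with an estimated correlation. It was -0.37 for hnRNP proteins (camera adjusted p = 6.2e-04) and -0.47 for megakaryocyte markers (camera adjusted p = 0.00629), each with 2 members adjusted over the list alone and adjusted p = 0.359 with an estimated correlation. Cholesterol synthesis at -0.62 (camera adjusted p = 0.00101) and the U2 snRNP list at -0.38 (2 adjusted over the list alone; camera adjusted p = 0.0188) had adjusted p = 0.724 with an estimated correlation. With the block heat shock genes at -0.37 were called too (camera adjusted p = 0.00969, and adjusted p = 0.624 with an estimated correlation). The share of reads outside annotated features was 33.6% in S34F and 25.1 ± 2.65% in Q157R cells, and it moved with these groups. In all 119 genes were called by edgeR, 64 higher and 55 lower in S34F. Each differed in the same direction between replicates 1 and between replicates 2, which a call on these same libraries favours. Over all genes the ratios of the 2 pairs correlated at 0.602. The block gave 4261, DESeq2 1237 and no filter 2135, and 0 were called with only these groups fitted or after leaving out S34F replicate 1 or 2 or Q157R replicate 1 or 2.

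Uninduced cells served as the control for induction. In the WT line, CD24, a surface glycoprotein, stood at 35.2 ± 19.5 CPM after induction and 6.03 ± 4.58 CPM before (SD, n = 2 each), and with the replicate block it rose 6.21-fold. LAMA5 rose 3.03-fold with the block, the platelet ATP receptor gene P2RX1 3.27-fold, TNXB 3.17-fold, the adhesion gene ICAM1 2.85-fold and NDUFV2 2.84-fold. CHML, a Rab escort protein gene, fell 2.36-fold, RELN 2.23-fold, the mitotic kinesin gene KIF23 2.13-fold, INTS13 2.06-fold and H3C1 1.95-fold. CCNB1, the mitotic cyclin B1, fell from 135 ± 9.59 to 69.4 ± 4.16 CPM, by -0.96 ± 0.14 with the block (edgeR adjusted p = 0.0215, range over the alternatives 0.0179 to 0.988). In the fit without the block CD24, ICAM1 and NDUFV2 were at 2.53, 1.57 and 1.54, but CD24 was at 1.81 and ICAM1 at 0.66 without induced WT replicate 2, and NDUFV2 at 0.94 without induced WT replicate 1. On the log2 scale P2RX1 ran from 1.033 to 2.585 over the alternatives, RELN from -1.727 to -0.6872 and H3C1 from -1.605 to -0.4691.

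Proliferation genes were lower in 40 of 40 cases after induction of WT, with a median of -0.66, 0 called and 21 adjusted over the list alone (camera adjusted p = 1.64e-33, and adjusted p = 0.0777 with an estimated correlation). With the block 8 of them fell, among them TOP2A at -0.78 and TYMS at -0.79. The hnRNP proteins had a median of -0.32, with 1 adjusted over the list alone (camera adjusted p = 2.06e-09, and adjusted p = 0.0777 with an estimated correlation), and HNRNPH3 fell 1.82-fold with the block. Medians were -0.23 for stress granule proteins (camera adjusted p = 1.92e-06), -0.17 for the U2 snRNP list (0.0023), -0.21 for SR proteins (0.0129), -0.22 for mitochondrially encoded mRNAs (0.0144) and -0.16 for oxidative phosphorylation (0.0203). They were +0.31 for NF-kB targets (0.0247) and +0.26 for cholesterol synthesis (0.0298), and these 7 lists each had adjusted p = 0.697 with an estimated correlation. ITGAM, BTG2 and FTX rose with the block, by 2.02-fold, 1.79-fold and 1.9-fold. With the block monocyte markers at +0.22 (camera adjusted p = 0.0162) and heat shock genes at -0.21 (0.0069) were called too, each with adjusted p = 0.562 with an estimated correlation. The share of reads outside annotated features also moved, from 19.2 ± 0.39% before to 22.7 ± 0.029% after induction. By edgeR without the block 0 of 21300 genes were called (1363 at an unadjusted p under 0.05). With the block 89 were called, 54 higher and 35 lower, DESeq2 called 18 and no filter gave 130.

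**Figure D3:**
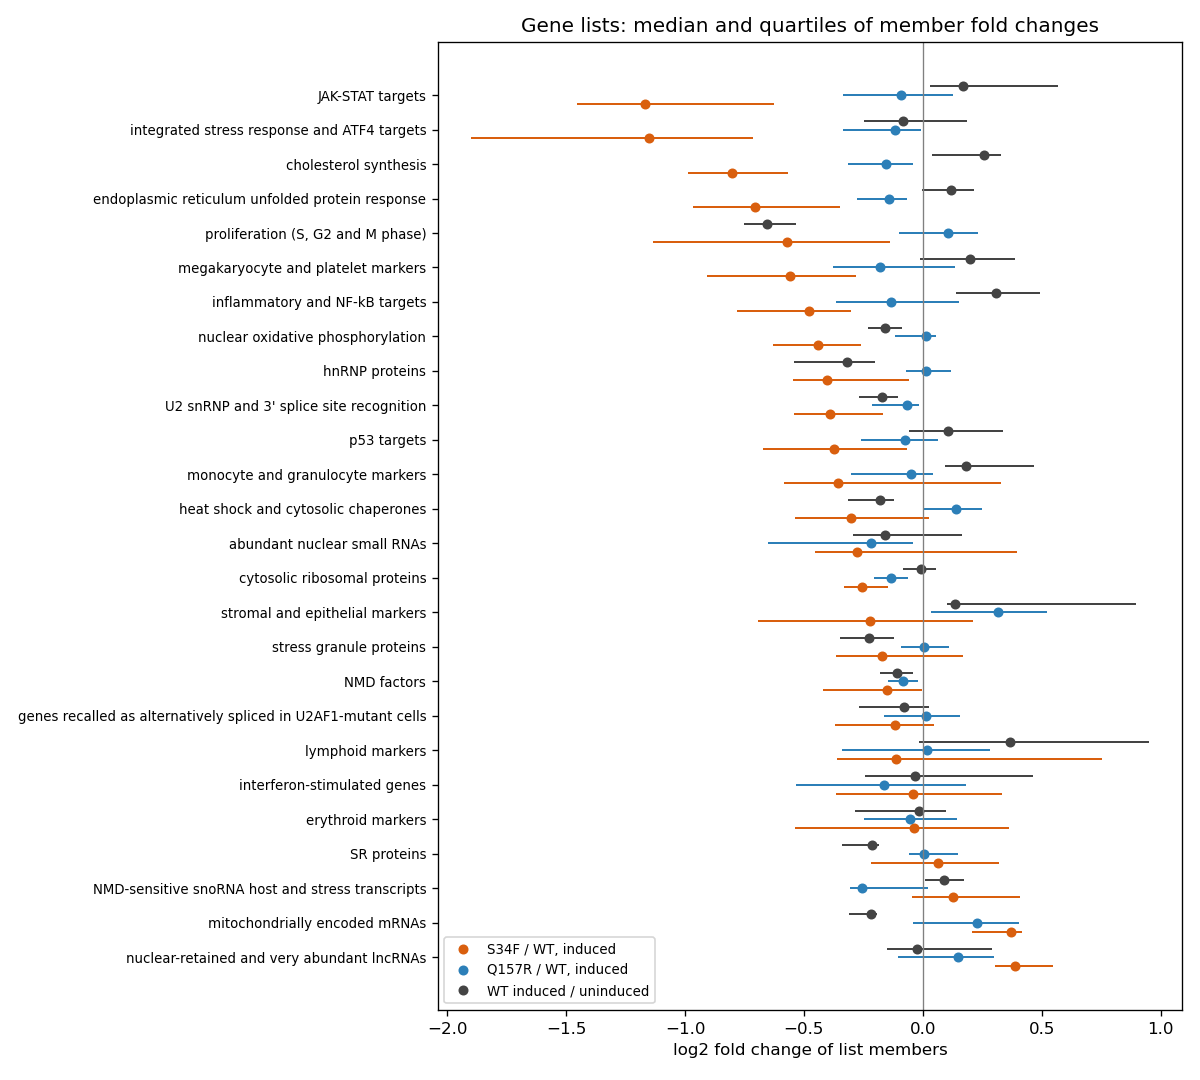
Log2 fold change of the members of each fixed gene list in 3 RNA-seq comparisons: S34F against WT, Q157R against WT, and induced against uninduced WT cells. Dots are medians and lines run from the lower to the upper quartile; JAK-STAT targets have a median of -1.17 and integrated stress response targets of -1.15 in S34F against WT.

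In the S34F line, induction raised AVIL 16.3-fold, TECTA 11.8-fold, PTGDR2, a prostaglandin D2 receptor gene, 9.22-fold, MGAM2 8.33-fold, ALPK3 8.14-fold and MSH4 7.88-fold (n = 2 induced against 1 uninduced library). MYEOV fell 5.82-fold, MARCKSL1 5.76-fold, CCND1 5.32-fold, CNN3 (calponin 3) 5.18-fold, the condensin gene NCAPG2 5.1-fold and H2BC10 5.07-fold. ITGAM rose 6.54-fold, from 5.38 to 35.2 ± 7.8 CPM, and KLRD1 and FAS rose by 5.95 and 4.77 on the log2 scale from 0.143 CPM each. Proliferation genes were lower in 40 of 40 cases with a median of -1.10, 8 called and 31 adjusted over the list alone (camera adjusted p = 2.37e-24, and adjusted p = 0.154 with an estimated correlation), TOP2A falling 3.03-fold, CCNA2 2.82-fold and MCM2 3.19-fold. Cholesterol synthesis genes were lower in 22 of 22 cases with a median of -1.18, FDPS being called and 13 adjusted over the list alone (camera adjusted p = 9.7e-09, and adjusted p = 0.528 with an estimated correlation). HNRNPAB fell 3.17-fold among hnRNP proteins (median -0.66, 13 adjusted over the list alone; camera adjusted p = 1.33e-06, and adjusted p = 0.154 with an estimated correlation). FTX rose 3.7-fold among lncRNAs (median +0.52, 2 adjusted over the list alone; camera adjusted p = 0.0245, and adjusted p = 0.361 with an estimated correlation).

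Further lists called for induction in the S34F line were oxidative phosphorylation at -0.58 (10 adjusted over the list alone; camera adjusted p = 1.33e-06), stress granule proteins at -0.30 with ELAVL1 called (7 adjusted over the list alone; 0.00173) and lymphoid markers at +0.38 (2 adjusted over the list alone; 0.0251), each with adjusted p = 0.528 with an estimated correlation. The ER unfolded protein response was at -0.89 (3 adjusted over the list alone; camera adjusted p = 8.59e-04, and adjusted p = 0.368 with an estimated correlation) and megakaryocyte markers at -0.61 (4 adjusted over the list alone; camera adjusted p = 0.00412, and adjusted p = 0.202 with an estimated correlation). The U2 snRNP list was at -0.57 (3 adjusted over the list alone; camera adjusted p = 8.59e-04) and NMD-sensitive transcripts at +0.49 (camera adjusted p = 0.0469), each with adjusted p = 0.614 with an estimated correlation. Heat shock genes were at -0.58 (camera adjusted p = 0.0118, and adjusted p = 0.735 with an estimated correlation) and JAK-STAT targets at -0.80 (camera adjusted p = 0.0171, and adjusted p = 0.714 with an estimated correlation). GFI1B fell 3-fold and STRAP 2.4-fold. The only uninduced S34F library is a replicate 1, so the fit without the block carries part of the difference between replicates. With the block NMD-sensitive transcripts (camera adjusted p = 0.0702), lymphoid markers (0.0925) and heat shock genes (0.0983) were no longer called, and integrated stress response targets at -0.81 were called (camera adjusted p = 3.37e-06, and adjusted p = 0.579 with an estimated correlation). The share of reads outside annotated features was 20.3% before induction and 33.6% after, and it moved with these gene groups. By edgeR 418 of 21300 genes were called, 150 higher and 268 lower. The block gave 4099, DESeq2 1787, no filter 2992 and only the S34F groups 4357, and 0 were called without induced S34F replicate 1 or without replicate 2.

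In the Q157R line CD24 stood at 67.3 ± 29.2 CPM after induction (n = 2) and 1.89 CPM before (n = 1), and with the block it rose by 4.40 on the log2 scale (edgeR adjusted p = 0.00105, range over the alternatives 4.33e-25 to 0.999). ICAM1 rose 6.12-fold with the block, MCF2L 4.86-fold, DOCK6 4.16-fold, ZNF467 3.99-fold and the pro-apoptotic gene BMF 3.72-fold. SAMHD1 fell 3.57-fold, HADHA 3.3-fold, CHML 2.85-fold, NCAPG2 2.77-fold, USP13 2.6-fold and RPAP3 2.56-fold. TYMS fell 1.88-fold and FTX rose 2.16-fold. Proliferation genes were lower in 39 of 40 cases with a median of -0.57, 0 called and 1 adjusted over the list alone (camera adjusted p = 4.47e-15, and adjusted p = 0.287 with an estimated correlation), as were hnRNP proteins at -0.42 (camera adjusted p = 4.61e-05, and adjusted p = 0.287 with an estimated correlation). Integrated stress response targets were higher in 25 of 27 cases with a median of +1.08, 0 called and 0 adjusted over the list alone (camera adjusted p = 6.56e-04, and adjusted p = 0.616 with an estimated correlation). The only uninduced Q157R library is a replicate 1, and this list was higher in replicate 2 by a median of +1.30, so that part of this value is a difference between replicates. With the block the median was +0.32, with 22 of 27 higher (camera adjusted p = 0.00432, and adjusted p = 0.731 with an estimated correlation).

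Other lists called for induction in the Q157R line were stress granule proteins at -0.27 (camera adjusted p = 4.61e-05, and adjusted p = 0.493 with an estimated correlation), monocyte markers at +0.69 (1 adjusted over the list alone; camera adjusted p = 0.00334) and lymphoid markers at +1.18 (camera adjusted p = 0.0226), both of these with adjusted p = 0.606 with an estimated correlation. The U2 snRNP list at -0.30 (camera adjusted p = 0.00194), heat shock genes at -0.53 (0.00194), SR proteins at -0.45 (0.00249), NF-kB targets at +0.64 (0.0081) and oxidative phosphorylation at -0.17 (0.0255) each had adjusted p = 0.616 with an estimated correlation. With the block oxidative phosphorylation (camera adjusted p = 0.221), lymphoid markers (0.0823) and heat shock genes (0.0571) were no longer called. Erythroid markers at -0.12 (camera adjusted p = 0.0265, and adjusted p = 0.694 with an estimated correlation) and stromal and epithelial markers at +0.66 (camera adjusted p = 0.0143, and adjusted p = 0.502 with an estimated correlation) then were. The share of reads outside annotated features also moved, from 20.6% before (n = 1) to 25.1 ± 2.65% after induction (SD, n = 2). By edgeR 0 of 21300 genes were called, with 1888 at an unadjusted p under 0.05. The block gave 56, 31 higher and 25 lower, DESeq2 69, no filter 569 and only the Q157R groups 8.

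The response to induction was then compared between lines. Relative to the WT line, the S34F line raised TECTA and AVIL more, by 3.70 ± 0.59 and 3.60 ± 0.47 on the log2 scale with the replicate block, and MSH4 and NAALAD2 by 2.21 each. The metalloproteinase-related gene ADAMTSL4 was at -3.10 with the block, the ETS factor gene ETV4 at -2.48, TIMP3 at -2.41 and UBASH3B at -2.39 ± 0.27 (edgeR adjusted p = 0.012, range over the alternatives 2.08e-08 to 0.936). The kinase genes PIM1 and PIM2 were at -1.73 and -1.49, DUSP6 at -1.76, GFI1B at -1.74, and the megakaryocyte genes RAB27B, ITGA2B and ITGB3 at -1.43, -1.23 and -1.18. ITGAM was at +1.49, SQLE at -1.73 and EDEM1 at -1.19. PSAT1 was at -1.81 with the block but at -0.25 without it (edgeR adjusted p = 0.977), and its direction turned without induced S34F replicate 1 (0.47), uninduced WT replicate 1 (0.50) or induced WT replicate 2 (1.18). Without that last library ADAMTSL4 was at -1.27, PIM1 at -0.51 and DUSP6 at -0.23 in the fit without the block.

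Cholesterol synthesis genes were lower in this difference in 22 of 22 cases, with a median of -1.33 (camera adjusted p = 3.82e-17, and adjusted p = 0.408 with an estimated correlation). Medians were -0.60 for proliferation genes (camera adjusted p = 4.16e-06, and adjusted p = 0.489 with an estimated correlation), -0.95 for the ER unfolded protein response (camera adjusted p = 4.16e-06, and adjusted p = 0.396 with an estimated correlation) and -0.71 for megakaryocyte markers with 1 adjusted over the list alone (camera adjusted p = 1.87e-05, and adjusted p = 0.17 with an estimated correlation). Oxidative phosphorylation at -0.43 (camera adjusted p = 3.92e-05) and JAK-STAT targets at -0.92 (camera adjusted p = 1.47e-04) had adjusted p = 0.615 with an estimated correlation. NF-kB targets were at -0.42 (camera adjusted p = 0.003, and adjusted p = 0.63 with an estimated correlation) and lncRNAs at +0.55 (camera adjusted p = 0.0288, and adjusted p = 0.408 with an estimated correlation). With the block integrated stress response targets at -0.83 (camera adjusted p = 4.75e-09, and adjusted p = 0.494 with an estimated correlation) and mitochondrially encoded mRNAs at +0.64 (camera adjusted p = 0.00448, and adjusted p = 0.76 with an estimated correlation) were called too. The share of reads outside annotated features moved with this difference, from 20.3% to 33.6% in the S34F line and from 19.2% to 22.7% in the WT line. By edgeR without the block 0 genes were called (1745 at an unadjusted p under 0.05), against 150 with the block, 19 by DESeq2 and 306 with no filter.

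For the Q157R line against the WT line, HADHA was called with the block, at -1.69 ± 0.20 (edgeR adjusted p = 0.0435, range over the alternatives 0.00641 to 1). Integrated stress response targets were higher in 25 of 27 cases with a median of +1.26 (camera adjusted p = 1.01e-05), which includes the difference between replicates, cholesterol synthesis was lower in 22 of 22 with a median of -0.42 (camera adjusted p = 1.15e-04), and mitochondrially encoded mRNAs had a median of +0.29 (camera adjusted p = 0.0335). These 3 lists each had adjusted p = 0.958 with an estimated correlation. With the block the integrated stress response median was +0.41, with 23 of 27 higher (camera adjusted p = 0.00203), and proliferation genes at +0.18 (0.0194) and the ER unfolded protein response at -0.20 (0.0216) were called too, each with adjusted p = 0.972 with an estimated correlation. By edgeR without the block 0 genes were called (261 at an unadjusted p under 0.05) and DESeq2 called 0, while no filter gave 44. Across all genes the S34F and Q157R effects against WT correlated at r = 0.309, where groups simulated without any change on the same WT libraries gave 0.478. The covariance was 0.128 against 0.156 simulated, and 0 genes were called in both. The simulated libraries varied independently, with a spread that includes the difference between replicates. In the data, like-numbered libraries deviated together, so the simulated values cannot tell whether the mutants share effects.

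The CLIP tables placed most counts on entries that lie opposite another gene. MT-ND6, the only mRNA encoded on the mitochondrial light strand, held 8363 eCLIP counts, where MT-CO1 held 764 and GAPDH 51. In freCLIP the counts were 18003 for MT-ND6, 642 for MT-CO1 and 85 for GAPDH, while in RNA-seq MT-CO1 held 1714321 and MT-ND6 89212. Entries with an opposite-strand gene took 84.84% of eCLIP and 83.13% of freCLIP counts, against 46.75% of RNA-seq counts, and made up 37.9% of entries. Across 9141 entries with at least 500 bases under 1 opposite-strand gene, eCLIP counts followed the RNA of the entry's own gene at a Spearman coefficient of 0.424 and that of the opposite gene at 0.683 (freCLIP 0.404 and 0.686; RNA-seq against its own opposite gene 0.212). CLIP values below are therefore given per entry, with the gene opposite it where the entry is first named, and do not say which of the pair was bound. An entry named without one has no gene opposite it, or only genes with clone names. For this naming an overlap of any length with the exons of the entry was enough.

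**Figure D4:**
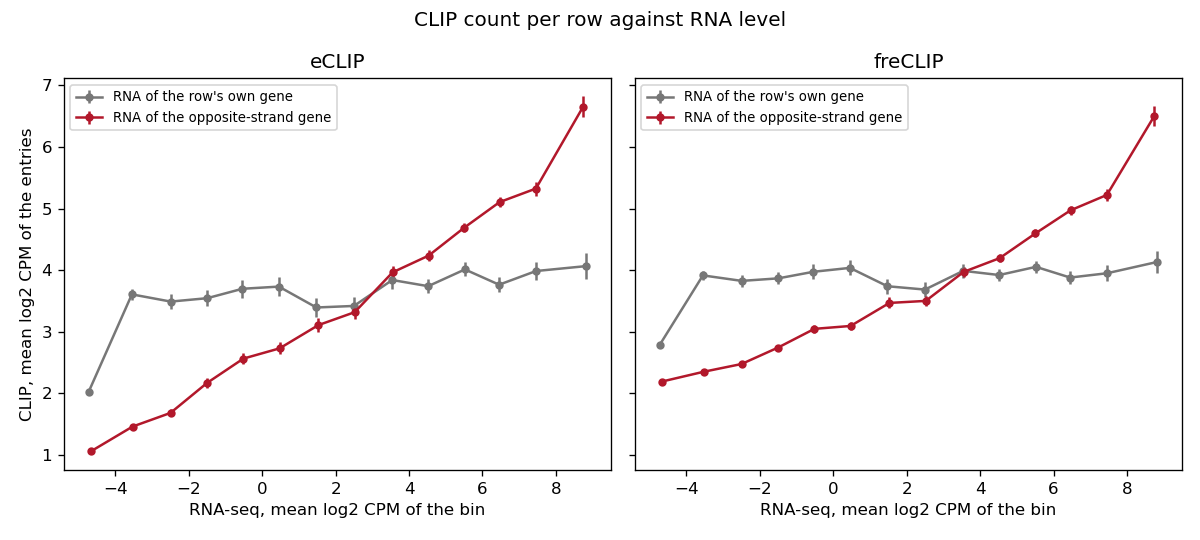
Mean log2 CPM of CLIP entries, with standard errors, against bins of the RNA-seq level of the entry's own gene (grey) or of the gene on the opposite strand (red), for eCLIP and freCLIP. The counts follow the opposite gene more closely, with Spearman coefficients of 0.683 and 0.686 against 0.424 and 0.404.

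U2AF1 eCLIP was set against U2AF2 eCLIP in WT cells. The U2AF1 libraries used anti-FLAG antibody and the U2AF2 libraries anti-U2AF2 antibody, and no control CLIP library was analysed. A difference between the subunits therefore cannot be told apart from one between the antibodies. All 13 mitochondrially encoded mRNA entries held more U2AF1 than U2AF2 signal, with a median of +1.58, 0 called and 13 adjusted over the list alone (camera adjusted p = 8.59e-20, and adjusted p = 0.955 with an estimated correlation). MT-ND6 (chromosome M, 14149 to 14673) had 5830 counts for U2AF1 and 2533 for U2AF2, a log2 difference of 1.58 ± 0.41 (edgeR adjusted p = 0.763, n = 2 each). Over the alternatives this difference ran from 0.9086 to 1.878. Nuclear-retained lncRNAs were at +0.86 with 5 of 6 higher, 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0415, and adjusted p = 0.955 with an estimated correlation), and not called with the block (camera adjusted p = 0.079). By edgeR 0 of 10521 entries were called, with 601 at an unadjusted p under 0.05, and DESeq2 called 0, while the block gave 11 and no filter 24. The U2AF1 replicates 1 and 2 correlated at a Spearman coefficient of 0.513, against 0.96 between the technical libraries of replicate 1, and without U2AF1 replicate 1 6523 entries were called, without U2AF1 replicate 2 2152, and without U2AF2 replicate 1 2.

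In the light fraction, S34F was compared with WT. The MROH1 entry (ENSG00000179832.17; chromosome 8, 144148016 to 144261940) held 308 counts in S34F and 25 in WT, 16.4-fold higher at 4.35 ± 0.63 (edgeR adjusted p = 5.76e-05; n = 3 each). Over the alternatives its log2 fold change ran from 3.918 to 6.096. HEATR9, opposite the RNA-binding protein gene TAF15, rose 26.4-fold (159 against 8 counts) and IGSF6, opposite METTL9, 13-fold. CC2D1B, opposite ZFYVE9, held 114 counts against 3 (ratio interval 16.9 to 249), and PDE6C and OR2B2 were at least 24.4-fold and 23.5-fold higher (55 and 53 counts against 0). These bounds and intervals leave out the spread between libraries. NEXN (ENSG00000162614.18; chromosome 1, 77888513 to 77943895), opposite NEXN-AS1, fell 4.96-fold, LINC00624, opposite CHD1L, 5.85-fold, and ABALON, opposite the apoptosis regulator BCL2L1, 2.75-fold. LMLN, opposite LMLN-AS1, fell 19.2-fold (4 against 102 counts), SLC24A3-AS1, opposite SLC24A3, held 2 counts against 108 (ratio interval 11 to 339), and MT-ND6 fell 2.06-fold at -0.997 ± 0.24 (edgeR adjusted p = 0.0399).

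MT-ND6 was the only one of 12 mitochondrially encoded entries called, also adjusted over the list alone (median -0.86, camera adjusted p = 0.138), and 0 of the 15 lists with enough entries were called. In all 23 of 6833 entries were called, 13 higher and 10 lower. No filter gave 11, DESeq2 96, only the compared groups 4 and entries under 1 opposite-strand gene 12, and there were 11 without S34F light replicate 1, 6 without its replicate 2, 14 without its replicate 3 and 6 without WT light replicate 4. RLE scaling moved the median of all entries by 0.115 and turned the split of calls to 19 higher and 7 lower.

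In the light fraction of Q157R cells, DST, opposite DST-AS1, was at least 140-fold higher than in WT (162 counts against 0, n = 2 against 3) and HADHA, opposite HADHB, at least 76.7-fold (89 against 0). Such bounds, here and below, cover counting error in the summed libraries and not the spread between libraries. That spread was far larger, with a chi-square per degree of freedom of 17.4 between the Q157R and 9.70 to 12.7 between the WT light libraries. The true differences may thus be smaller than the bounds. PARP9 (opposite DTX3L), JUND and FUT11 were at least 20.7-fold, 15.5-fold and 15.5-fold higher, and IQCH, opposite AAGAB and IQCH-AS1, held 87 counts against 4. SEC22C, opposite SS18L2 and NKTR, was at least 29.1-fold lower (0 counts against 226). PKD2L2 (opposite PKD2L2-DT and FAM13B) and STX5-DT (opposite WDR74) were at least 22.1-fold lower, UBE2D4 (opposite POLR2J4) at least 19.1-fold, and GPANK1 (opposite CSNK2B) and GABRA3 at least 15.7-fold. Of 6 oxidative phosphorylation entries 2 fell, also adjusted over the list alone: NDUFB10 was at least 9.8-fold lower, and ATP5PB, opposite WDR77, held 2 counts against 237 (ratio interval 12.6 to 381). Of 6 p53 target entries 3 fell, also adjusted over the list alone: TP53I3 (opposite FAM228B) and PLK3 (opposite DYNLT4) were at least 11.2-fold and 7.61-fold lower, and POLH, opposite GTPBP2, held 6 counts against 182. POLH was at -2.88 (edgeR adjusted p = 0.0482), but at -1.56 and not called without Q157R light replicate 3, at -9.22 without Q157R light replicate 2, and not called without WT light replicate 3, with RLE scaling, with no filter or with only the compared groups (highest adjusted p = 0.661).

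The interferon-related entry IRF7 fell (2 counts against 107, ratio interval 5.59 to 173), as did DNAJB1 (at least 11.5-fold lower, opposite TECR), ATG7 (6.66-fold, opposite VGLL4) and FTX (2.85-fold, opposite JPX and others). Of the 15 lists 0 were called by camera, the lowest adjusted p being 0.904. By edgeR 519 of 6833 entries were called, 92 higher and 427 lower, around a median of -1.19 over all entries. The 2 Q157R light libraries behind these calls correlated at a Spearman coefficient of -0.0477, against 0.199 to 0.305 between WT and 0.322 to 0.544 between S34F light libraries. Each was taken over entries with at least 10 counts in the pair, 2916 for Q157R, 4778 to 7169 for WT and 4339 to 5937 for S34F. Choosing entries by their summed count can lower a coefficient, most of all in sparse libraries, so these values are not fully alike. RLE scaling moved that median by 0.361 and raised the share of higher calls to 36.7%, with 365 called. The block gave 333, no filter 263, entries under 1 opposite-strand gene 294 and only the compared groups 0, and there were 1318 without Q157R light replicate 2 and 137 without Q157R light replicate 3.

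In the heavy fraction, HEATR9 (438 against 79 counts, 8.43-fold), MROH1 (732 against 168, 6.63-fold) and ZFHX4 (508 against 126, 6.13-fold, opposite ZFHX4-AS1) were higher in S34F than in WT, MROH1 at 2.49 ± 0.50 (edgeR adjusted p = 0.0317; n = 3 against 4). ADAMTSL4, opposite ADAMTSL4-AS1 and ADAMTSL4-AS2, rose 4.35-fold and MFSD12, opposite FZR1 and others, 3.3-fold, and IL21R, a cytokine receptor gene opposite IL21R-AS1, held 191 counts against 1 (ratio interval 51.5 to 11500). MARCHF1 fell 2.41-fold (1662 against 6080 counts). The 12 mitochondrially encoded entries were all lower, with a median of -0.82, 0 called and 1 adjusted over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.797 with an estimated correlation), and with the block the list was not called (median -0.51, camera adjusted p = 0.112). In all 9 entries were called by edgeR, 6 higher and 3 lower. The block gave 17, DESeq2 36, no filter 1, entries under 1 opposite-strand gene 3 and only the compared groups 240, and leaving out any S34F library or WT replicate 2, 3 or 4 gave 0 and leaving out WT replicate 1 gave 2. With RLE scaling the 6 calls were all higher. For Q157R against WT in the heavy fraction 0 entries were called by edgeR and 0 by DESeq2, with 149 at an unadjusted p under 0.05.

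Light and heavy fractions of WT cells were compared to separate the signal of U2AF1 from that of its complex. MT-TQ, a mitochondrial tRNA opposite MT-TI, was 3.71-fold higher in the light fraction (1426 against 1064 counts at unequal depth), and MT-ND6 2.14-fold higher at 1.16 ± 0.22 (edgeR adjusted p = 0.00702; n = 3 against 4). CC2D1B held 3 counts against 192 (ratio interval 7.78 to 113). In all 5 of 6833 entries were called, 4 higher and 1 lower. DESeq2 gave 12, nuclear chromosomes only 3 and entries under 1 opposite-strand gene 1, and there were 2 without WT heavy replicate 1, 3 without WT light replicate 2, 2 without its replicate 3 and 2 without its replicate 4.

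The difference between fractions did not separate S34F from WT at any entry by edgeR (0 called, 321 at an unadjusted p under 0.05, DESeq2 0). For Q157R minus WT 63 entries were called, 5 higher and 58 lower, with MROH1 at 3.43 and IRF7 at -4.59. Over the alternatives MROH1 ran from 1.71 (without Q157R light replicate 3) to 5.09 (without WT light replicate 3) with adjusted p up to 0.472, and IRF7 from -8.72 (without Q157R light replicate 3) to -4.10 (without Q157R light replicate 2) with adjusted p up to 0.22. DESeq2 gave 154, RLE scaling 19, no filter 17, entries under 1 opposite-strand gene 34 and only the compared groups 1, and there were 707 without Q157R light replicate 2, 129 without WT light replicate 2, 40 without Q157R light replicate 3, and 22 to 28 without Q157R heavy replicate 3 or any WT heavy replicate. In the light fraction 3 entries were higher and 2 lower in both mutants, where independent lists of these sizes would share 0.175 and 0.625, and groups simulated without any change on the same WT libraries shared 0.2 and 0.15 on average and at most 2 in each direction over 20 draws. Neither number holds both the effects and the shared libraries, so part of this overlap may come from the WT libraries. The effects correlated there at r = 0.293 against 0.382 in simulated unchanged groups, with a covariance of 2.01 against 0.714. In the heavy fraction r was 0.131 against 0.341 and the covariance 0.169 against 0.51, and they were -0.0516 and -0.0934 when each mutant had its own part of the WT libraries.

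Light-fraction counts were last set against the RNA of the same entry. Since freCLIP counts followed the opposite gene more closely, this does not remove the effect of expression, and with the RNA of the opposite-strand gene edgeR called 0 of 6175 entries for either mutant (461 for S34F and 847 for Q157R at an unadjusted p under 0.05). Mitochondrially encoded mRNAs had a median of -0.94 in S34F against WT with 10 of 13 lower, 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0289, and adjusted p = 0.923 with an estimated correlation), and with the block the list was not called (median -0.50, camera adjusted p = 0.49). By edgeR 0 of 11759 entries were called for S34F (1042 at an unadjusted p under 0.05) and 0 for Q157R (1173). DESeq2 called 172 and 125, the block 101 and 179, and voom with a variance per assay 0 and 0. Without Q157R light replicate 2 there were 136 for Q157R.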

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

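Of the tests given here, the comparison of olfactory receptor reads above the WT level, those on the Q157R light libraries and that on the strand of the CLIP counts were chosen after the result was seen.

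Reads outside annotated features made up 33.56% of the reads in induced S34F RNA-seq libraries, against 22.7% in induced WT libraries, which is a signal in reads that the comparisons do not use. Genomic DNA would put reads on olfactory receptor genes, and these held up to 1.59 times the number expected from the excess, which met the 1 set in advance, but it was then seen that induced WT libraries held 0.0195 and 0.0215 such reads per kb at equal depth, more than the 0.0178 that the excess would give, so that this ratio decides nothing. S34F libraries held 0.0275 and 0.0277, and counted above the lower WT level the ratio was at most 0.466, under the bound of 0.5. The uninduced S34F library, however, held 0.0139, below the induced WT levels, and a lower starting level gives a higher ratio. The result thus depends on the level chosen, so it does not decide whether genomic DNA gave part or all of the excess. More intronic RNA remains open: entries annotated as sense-intronic had a median log2 fold change 0.263 ± 0.0506 above that of lincRNA entries, above 0 but under the 0.3 set in advance, so that it cannot be told apart from a rise of noncoding RNA in general. The S34F protein itself may raise such reads by a biological route, which was not tested, and the replicates of S34F do not separate genotype from library preparation.

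The light fraction of Q157R cells differed from that of WT cells at 519 entries, and in the difference between fractions at 63 entries, a test of whether the fractions moved apart by genotype. WT light libraries thinned to the depth of the shallowest Q157R light library showed at least 1.25 times its entries with a count, under the 1.5 set for excluding depth. A gap left at equal depth is not one of depth, but it rests on 1 Q157R library. Replicate 3, at 135596 counts, showed 4934 entries with a count where WT replicate 2 showed 6683 at 78987 counts, which goes against depth for that gap. Entries with a count are not the calls, so whether depth added to the 519 calls stays open. For fewer distinct molecules in both Q157R light libraries, the share at 0 was taken among entries with at least 5 counts expected from the WT heavy fraction. The lower share in Q157R minus the highest in WT was -2.23 percentage points, against the prediction. However, it covered 1639 entries in Q157R replicate 2 and 3216 to 7947 in WT libraries, so the shares are not alike. Thinned to 38415 counts, the Q157R libraries showed 4619 and 3558 entries, against 5757 to 7899 in the other light libraries. This explanation therefore stays open. In Q157R light replicate 3, however, the share at 0 was 48.7%, 27.1 points above the highest of the other 7 light libraries, consistent with few distinct molecules in that library. A binding change caused by Q157R stays open, since leaving out either Q157R light library left 1 in the group. The 2 correlated at a Spearman coefficient of -0.0477, over 2916 entries chosen by their summed count, which can lower it.

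Counts in the CLIP tables lay mostly on entries with a gene on the opposite strand. The Spearman coefficient with the RNA of the opposite gene exceeded that with the entry's own RNA by at least 0.259 in both tables, consistent with reads counted on the strand opposite to the crosslinked RNA. Crosslinking to antisense transcripts themselves is less likely to give 8363 eCLIP counts on MT-ND6 beside 764 on MT-CO1, but no table held counts for the other strand, so this was not tested. If the strand is turned, a change at an entry may belong to the gene opposite it. An overlap of any length was enough to name such a gene, and some entries have several, so the reads need not come from the gene named. Entries with no gene opposite them cannot be assigned.

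Other splits of the same libraries were used to ask whether libraries grouped at random give as many calls. In the light fraction, the real split of 3 S34F and 3 WT libraries gave 23 entries and the highest of the others 10, 1 of 10 splits reaching the real value, which is too few splits for a share under 0.05. In the heavy fraction the real split gave 9 and the highest other 0. This was 1 of 35 splits, a share under 0.05 and the lowest that 35 splits can give. The calls fell to between 0 and 2 on leaving out single libraries. Chance is thus less likely for this count but not excluded. Between light and heavy WT libraries 2 of 35 splits gave as many as the real 5 (highest other 7), so that chance cannot be excluded. For the fraction difference of S34F minus WT the real value was 0, which every split reaches (100 of 100), so that this count says nothing on chance; the highest other was 138, and whether a structure of the libraries gave it was not tested.

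In the difference between fractions for Q157R minus WT, the fitted values were 14.95 for VDR, 14.42 for CIC, 13.11 for DST and 3.43 for MROH1. They were -9.53 for SEC22C, -9.36 for PKD2L2, -9.11 for ITGB8, -8.96 for FBXL2, -8.58 for DNAJB1, -6.07 for ATP5PB and -4.59 for IRF7. Those of VDR, CIC, DST, SEC22C, PKD2L2, ITGB8, FBXL2 and DNAJB1 rest on groups with no counts, depend on the prior count and are no bounds. The value of ATP5PB ran from -10.57 to -4.453 over the alternatives. FBXL2 lies opposite UBP1 and ITGB8 opposite ITGB8-AS1. VDR held 0 and 205 counts in the 2 Q157R light libraries, and CIC 0 and 130. These entries appear here because the test of the difference between fractions passed. For IL21R, 1 WT heavy library was set apart by its gap to the other 3, at 4.23 log2 CPM, but it held 1 count against 0 in each of them, which counting error alone can give, and chance picks out about 1 in 20 groups at this limit.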

How the results depend on the processing

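The replicate block with GC content and exon length, entries under 1 opposite-strand gene and the technical libraries in place of U2AF1 replicate 2 were chosen after seeing the data, and the cause of the changes below was not tested except where fewer samples or genes enter a fit. Genes called by edgeR were, for S34F against WT (356), 4779 with the replicate block, 4417 with block, GC content and exon length, 2410 with no filter, 1567 by DESeq2 and 0 with only these groups. They were 4, 4, 15 and 3 for Q157R against WT (0), in the order block, block with GC and length, no filter and DESeq2. For S34F against Q157R (119) they were 4261, 4176, 2135, 1237 and 0 with only these groups, and for WT induction (0) 89, 167, 130 and 18. For S34F induction (418) they were 4099, 3986, 2992, 1787 and 4357 with only these groups, and for Q157R induction (0) 56, 95, 569, 69 and 8. The difference of the S34F line (0) gave 150, 103, 306 and 19, and that of the Q157R line (0) 1, 1 and 44. Each RNA comparison gave 0 to 0 on leaving out single libraries, where a lone library is assumed to vary like the other groups. RLE scaling kept every RNA count within 1.5 times. In light S34F (23) the counts were 11 with no filter, 96 by DESeq2, 4 with only these groups, 12 under 1 opposite-strand gene and 6 to 28 without single libraries. In light Q157R (519) they were 333 with the block, 263 with no filter, 0 with only these groups, 294 under 1 opposite-strand gene and 137 to 1318. In heavy S34F (9) they were 17 with the block, 1, 36 by DESeq2, 240, 3, 6 with RLE and 0 to 2, and heavy Q157R stayed at 0 (0 to 0). Light against heavy WT (5) gave 12 by DESeq2, 3 on nuclear chromosomes, 1 under 1 opposite-strand gene and 2 to 5. The fraction difference of S34F stayed at 0 (0 to 0), and that of Q157R (63) gave 19 with RLE, 17, 154, 1, 34 and 22 to 707. eCLIP (0) gave 11 with the block, 24 with no filter, 3118 with the technical libraries in place of U2AF1 replicate 2 and 0 to 6523. Light fraction relative to RNA (0) gave 101 with the block, 172 by DESeq2 and 0 to 0 for S34F, and 179, 125 and 0 to 136 for Q157R. With an estimated correlation 0 lists were called in any comparison, and the block changed the lists called to 4 for Q157R against WT, 5 for the Q157R difference, 0 in heavy S34F, 1 in eCLIP and 0 in S34F relative to RNA. Directions that reversed on leaving out single libraries concerned genes not called by edgeR with or without that library: U2AF1 ranged from -0.0516 to 0.764 for S34F against WT, from -0.05778 to 0.7346 for Q157R against WT and from -0.2429 to 0.5442 for WT induction, PHGDH from -2.432 to 0.01324 for S34F against WT, PSAT1 from -1.99 to 1.179 for the difference of the S34F line, and, for Q157R against WT, U2AF2 from -0.3941 to 0.09834, MKI67 from -0.2261 to 0.3554, RPS6 from -0.3233 to 0.1483 and RPL4 from -0.4004 to 0.1265. Alternatives that kept all libraries reversed 0 of the named genes. Of the values of named genes by DESeq2, 165 kept their side of the threshold, 40 passed it and 4 no longer did; with RLE these were 200, 0 and 10, with the block 120, 78 and 12, with no filter 119, 63 and 28, with only the compared groups 120, 4 and 76, and without single libraries 565, 4 and 372 with 14 reversed. In freCLIP 6 of 34 pairs with the same number had correlations over 0.1 (0.00176 to 0.145), and 13 of 34 among entries with over 200 summed counts (0.0045 to 0.244). All of these were above 0, so that pairing by number was weak in freCLIP but is not excluded. In eCLIP 0 of 2 pairs were over 0.1. Both had the same coefficient of 0.0757, since the deviations of 2 replicates mirror each other. Depth limits what the light fraction can show, where libraries hold as few as 38415 counts.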

Other observations

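The group of replication-dependent histone genes and the test between replicates were chosen after values had been seen, the histone genes because members stood among the largest falls, and the group was not tested against other genes. Of 59 replication-dependent histone genes, 18 fell and 0 rose in S34F against WT with a median log2 fold change of -1.03, and 46 fell with the replicate block. In S34F induction 24 fell with a median of -1.43 (49 with the block). In WT induction 0 were called with a median of -0.60 (2 fell with the block), and in Q157R against WT 0 were called with a median of -0.18. Transcripts by annotation type moved apart in S34F against WT, with medians of +0.70 for sense-intronic, +0.44 for lincRNA and +0.37 for antisense entries, and -0.16 for protein-coding genes. This shift bears on the gene lists called in that comparison. Medians by type were not computed for the other comparisons.

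Replicates 1 and 2 of RNA-seq differed at 3635 of 21300 genes, 1938 higher and 1697 lower in replicate 2 (edgeR, adjusted p under 0.05). Integrated stress response and ATF4 targets were higher in replicate 2, with 24 of 27 members called and a median of +1.30 (camera adjusted p = 3.46e-43, and adjusted p = 0.385 with an estimated correlation). The serine synthesis genes PSAT1 and PHGDH were higher by 2.14 and 2.00 on the log2 scale, CHAC1 by 2.72, GPT2 by 2.26 and the integrin gene ITGB2 by 2.92. Heat shock genes were lower, with a median of -0.72 (camera adjusted p = 1.46e-17, and adjusted p = 0.385 with an estimated correlation).

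With lists assigned by the gene opposite each CLIP entry, integrated stress response targets in the heavy fraction of S34F against WT had a median of -1.25 over 9 entries (camera adjusted p = 3.05e-04, and adjusted p = 0.0752 with an estimated correlation). JAK-STAT targets had a median of -0.96 over 5 entries (camera adjusted p = 0.00516, and adjusted p = 0.0752 with an estimated correlation). Several entries can lie opposite the same gene, and camera at its preset correlation takes them as separate members. The number of distinct genes behind these entries is not given here. In the light fraction JAK-STAT targets were at +0.587 (camera adjusted p = 0.335) and integrated stress response targets at -0.996 (0.0813). No other list assigned in this way was called in any CLIP comparison. RNA of both lists was also lower in S34F, so a change in expression cannot be told apart from one in binding. With the RNA counts of the opposite-strand gene in the joint fit, which holds the light fraction and not the heavy one, 0 entries were called for either mutant.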
